A study of Ovis aries with 9 samples.

How the data were processed

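The samples were hepatocytes from the livers of female sheep (Ovis aries), 1 sample per stage: virgin, 6 ranges of gestational days, and days 7 and 15 after birth with lactation. Per the labels' protocols, livers of slaughtered sheep were kept cold, cut up and digested with collagenase, cells were picked by hand under a microscope, and each cell received its own Smart-seq3xpress library. Per the submitters' processing notes, Trimmomatic 0.39, HISAT2 2.1.0 and featureCounts 2.0.1 were used. The genome build is not given in the sources used here, and neither the labels nor the table say whether molecular identifiers were collapsed. The values are therefore treated as read counts, as the authors' file is named. The values used here are whole-number counts per gene and cell as the authors deposited them, with no normalization. Cell stages came from the column names, which matched the authors' cell sheet for 3404 of 3404 cells. A table of normalized values held 0 values other than NA and was not used.

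The count table held 28861 rows, of which 24 named no gene and carried 0.474% of reads. These stayed out of library sizes and tests. All 28837 gene symbols were found in the RefSeq gene table of assembly ARS-UI_Ramb_v3.0, which was used only for names and for which genes are neighbours, and no coordinates are given. Of the symbols, 12262 start with LOC. The table had rows for 0 of the 13 mitochondrial protein-coding genes, so the list of mitochondrial genes was not tested. No cell was left out of the sums. A filter planned as an alternative, on a minimum of genes detected and a maximum share of mitochondrial reads, removed 0 cells, since the cell with the fewest rows detected had 4000 and no mitochondrial rows were there to count. Reads per cell ran from 36518 to 3842012. Doublets were not called, since cells had been picked singly by hand. No cells were clustered or typed, and marker lists of other cell types served as a check.

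Counts were summed over the cells of each sample. The fit used edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment, threshold 0.05) with a term per phase over all 9 stages, so that the phases share 1 estimate of the spread. The contrasts were gestation against lactation, gestation against virgin and lactation against virgin. The trend was fitted over the 6 gestation stages on the midpoint of each range of days, per 100 days. The gestation to lactation step across birth has 1 library on each side, so CPM with exact Poisson intervals and list medians among 10000 random lists matched on expression are given in place of a test.

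Before the data were examined, 43 gene lists were fixed, covering metabolism, secretion, hormone and stress responses, growth and markers of hepatocytes and other liver or blood cells. In each contrast 42 were tested with fry and camera of limma 3.58.1 (preset correlation 0.01, and estimated). Fry asks whether the members move one way on balance and does not compare the list with other genes, and a list that passed fry passed this form. The mixed form of fry, planned as well, asks whether members change in either direction. At an adjusted p under 0.05, 18 lists passed it between gestation and lactation, 4 between gestation and virgin, 6 between lactation and virgin and 15 for the trend. Stage medians used members of at least 5 CPM on average and log2(CPM + 1), which 35 lists of 3 or more such members allowed. Genes are named by a rule fixed at the same time. In each contrast these are up to 12 genes per direction with the largest fold change among those with a symbol other than LOC, an adjusted p under 0.05, at least 20 CPM on the higher side, and samples that do not overlap (for the trend, a Spearman rho of at least 0.8 in size). For each list these are up to 4 called members, or else the 2 with the highest expression. Across birth these are the 8 genes per direction with the largest fold and at least 50 CPM in the higher stage. Any other gene is marked as chosen after its values were seen. Not every gene that the rule names is reported here.

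For measures over cells each cell was thinned to 155164 reads, the 10th percentile of reads per cell, which kept 3063 cells and left out 341 with fewer. By stage, in the order virgin, gestation by day, and lactation by day, 50, 26, 37, 40, 41, 13, 55, 21 and 58 cells were left out. The zonation measure is the Spearman correlation across cells of the mean log2(CPM + 1) of pericentral and periportal genes. Stage values were compared with two-sided exact permutation tests, enumerating all 28 arrangements of the 8 stages. Shares have exact (Clopper-Pearson) 95% intervals. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

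The fits were tested on simulated counts in which 67, 67 and 66 genes had been changed by a log2 of 1, 2 and 3. Between gestation and lactation 3.0%, 80.6% and 86.4% of them were called, with 8 false calls among 121 over 19407 genes. Between gestation and virgin the shares were 3.0%, 46.3% and 80.3% (5 false of 91, 19428 genes), between lactation and virgin 0%, 17.9% and 54.5% (8 of 56, 19406 genes), and for the trend 0%, 37.3% and 68.2% (3 of 73, 17212 genes). A change of 2-fold was thus seldom called.

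The alternatives fixed beforehand were DESeq2 size factors, library size as the only scaling, no filter on low counts, the DESeq2 1.42.0 Wald test, equal weight per cell with limma, cells thinned to 1 depth, the filter on cells given above, haemoglobin genes left out of library sizes, each stage left out in turn, stage order in place of days, the virgin sample added at day 0, an estimated correlation in camera, and other depths and scores for the measures over cells. A filter requiring enough counts in every gestation stage was added after the data were seen.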

Results

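Hepatocytes from the livers of female sheep were profiled one cell at a time with Smart-seq3xpress, a plate-based method that makes a separate full-length library from each hand-picked cell. The series sets 6 stages of gestation and 2 stages of lactation beside virgin ewes, and it asks how the hepatocyte adapts in each state. Each stage was 1 sample, so the groups held 1 virgin, 6 gestation and 2 lactation samples. The count table held 3404 cells. The virgin sample had 531 cells and 261815503 reads on named genes. The gestation samples, in order of day, had 291 cells and 133692777 reads (days 40 to 50), 289 cells and 122222238 (days 50 to 70), 253 cells and 121865640 (days 70 to 80), 396 cells and 213670593 (days 90 to 100), 353 cells and 173491742 (days 100 to 120), and 492 cells and 204863071 (days 140 to 150). The lactation samples had 246 cells and 114865665 reads at day 7 and 553 cells and 272944124 at day 15. Reads were summed over the cells of a sample and compared between samples. The labels name no separate animals, so p-values measure only the spread between these stages, with 1 library per stage. Intervals on single samples cover counting error only. Levels are given in CPM (counts scaled to the TMM-adjusted total of the sample), with the SD over the samples of a phase.

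The gene with the smallest adjusted p between gestation and lactation was HMOX1, the enzyme that opens the heme ring. It stood at 40.6 ± 2.31 CPM in lactation (SD, n = 2), 7.11 ± 1.76 CPM in gestation (n = 6) and 5.34 CPM in the virgin sample. The gestation level was thus 5.70-fold lower, with a log2 fold change of -2.51 (SE 0.22, adjusted p = 0.00785, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). NCMAP, named after a protein of noncompact myelin, was lower in gestation as well, at 5.73 ± 1.75 against 29.6 ± 8.50 CPM (log2 fold change -2.37, SE 0.29, adjusted p = 0.0381, edgeR). AASS, which carries out the first steps of lysine breakdown, was higher in gestation at 44.1 ± 7.32 against 14.1 ± 0.355 CPM (1.64, SE 0.20, adjusted p = 0.0381, edgeR). CHIA, an acidic chitinase, was higher in gestation at 141 ± 42.4 against 21.5 ± 5.40 CPM (2.71, SE 0.37, adjusted p = 0.0414, edgeR). For each of these 4 genes no gestation sample overlapped a lactation sample, which the naming rule required.

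**Figure D1:**
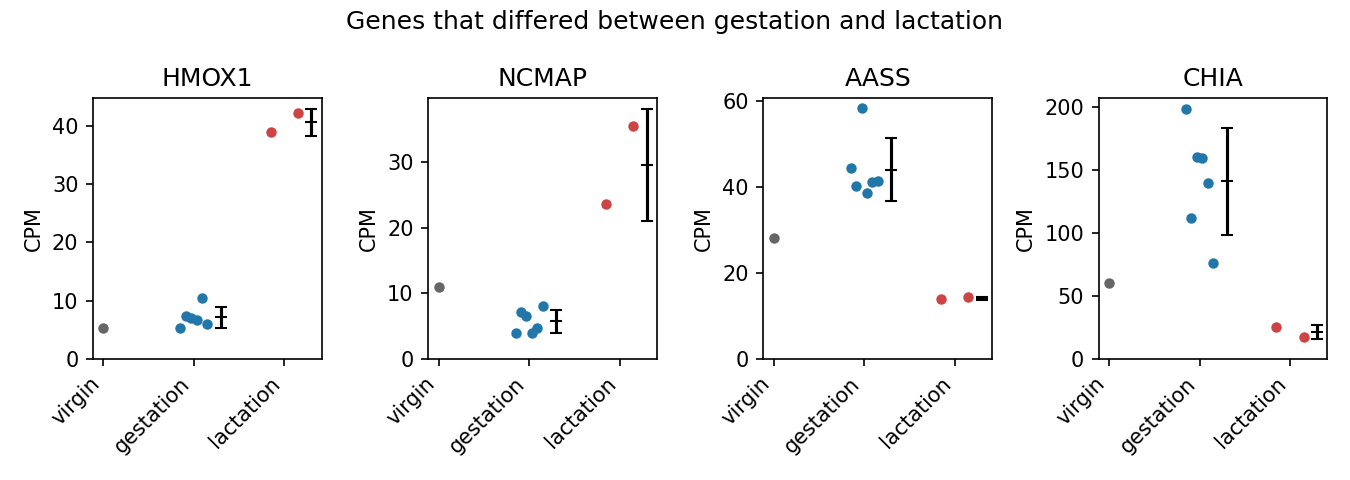
CPM of HMOX1, NCMAP, AASS and CHIA in each sample (points: grey virgin, blue gestation, red lactation), with the mean and SD of the gestation and lactation samples as bars. HMOX1 lay at 38.9 and 42.2 CPM in lactation and at 10.4 CPM or lower in every gestation sample.

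In total 12 of 20263 genes differed between gestation and lactation in edgeR at an adjusted p under 0.05, 6 higher and 6 lower in gestation, and 1905 had an unadjusted p under 0.05. The balance of directions changed with the processing, to 6 higher and 16 lower with library size as the only scaling, 0 and 6 with equal weight per cell in limma, and 355 and 168 with DESeq2. The other 8 lay outside the naming rule, and those named here were chosen after their values were seen. CARS1, the cysteinyl-tRNA synthetase, was lower in gestation (log2 fold change -1.38, SE 0.19), as were UNKL (-1.27, SE 0.17) and C1H21orf62 (-3.51, SE 0.48). LOC101110467 was lower in gestation, at 15.3 ± 4.31 against 63.4 ± 15.3 CPM. LOC106990219, LOC114108708 and LOC101108092 were higher in gestation. They lie close together in the RefSeq gene order, with 1 gene between the first 2 of them and 0 between the last 2, and whether they share reads as copies of one another was not tested, so their single values are uncertain. LOC101108092 stood at 274 ± 130 CPM in gestation and 6.67 ± 4.81 CPM in lactation. HTR2A, a serotonin receptor, was called at 1.09 CPM in gestation and 0.0180 CPM in lactation, levels that rest on few reads.

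Amino acid breakdown was the gene group with the smallest fry p between gestation and lactation. Of its 35 measured members, 33 were higher in gestation and the list passed fry (adjusted p = 0.00621, and adjusted p = 0.0147 with an estimated correlation in camera). Over all genes 1 member was called (AASS), and adjusted over the list alone 9 were higher and 1 was lower. Members chosen after their values were seen included DBT, of the branched-chain keto acid dehydrogenase (log2 fold change 1.15, SE 0.21), BHMT, which remethylates homocysteine (1.13, SE 0.21), and HPD, of tyrosine breakdown (0.92, SE 0.24). The member that was lower was GLUD1, glutamate dehydrogenase (-0.74, SE 0.22, and -0.48 without the library of day 15 of lactation).

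Urea cycle and periportal genes, active where portal blood enters the lobule, were higher in gestation too. In the urea cycle list 8 of 10 members were higher (fry adjusted p = 0.0225, and adjusted p = 0.093 with an estimated correlation in camera). No member was called over all genes, and adjusted over the list alone 5 were higher and 1 was lower. CPS1, the entry enzyme of the cycle, had a log2 fold change of 1.12 (SE 0.22), and GLS2, the liver glutaminase, chosen after its values were seen, had 2.27 (SE 0.40). In the periportal list 19 of 21 members were higher (fry adjusted p = 0.043, and adjusted p = 0.093 with an estimated correlation). This list shares 5 members with the urea cycle list and 5 with the amino acid breakdown list, so the lists are not separate evidence. Adjusted over the periportal list alone 8 were higher, against 0 called over all genes, with SLC7A2, a transporter of basic amino acids chosen after its values were seen, at a log2 fold change of 1.31 (SE 0.26). The list of hepatocyte markers moved with these groups, with 12 of 13 higher in gestation (fry adjusted p = 0.0384, and adjusted p = 0.123 with an estimated correlation). Albumin (ALB) stood at 97970 ± 8696 CPM in gestation, 40020 ± 11340 CPM in lactation and 80631 CPM in the virgin sample, and 2 markers were higher adjusted over the list alone, against 0 over all genes.

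Genes of steroid hormone handling were higher in gestation on balance, with 9 of 13 members higher (fry adjusted p = 0.0263, and adjusted p = 0.123 with an estimated correlation in camera). The median log2 fold change of 0.24 went to 0.05 with library size as the only scaling (fry adjusted p = 0.268) and to 0.02 with equal weight per cell in limma (adjusted p = 0.229), and to 0.54 without the library of day 15 of lactation (adjusted p = 0.0387). Adjusted over the list alone 2 were higher and over all genes 0. They were NR3C2, the mineralocorticoid receptor, at a log2 fold change of 3.57 (SE 0.67), and SRD5A2, a steroid 5-alpha-reductase, at 1.62 (SE 0.37, with 1.05 without the library of day 15 of lactation and 2.59 without that of day 7), both chosen after their values were seen. The level of NR3C2 was low even in gestation, at 0.529 to 1.39 CPM, so its fold change is uncertain. Neutrophil markers were lower in gestation in 5 of 5 members (fry adjusted p = 0.0263, and adjusted p = 0.093 with an estimated correlation), with 2 lower adjusted over the list alone and 0 over all genes. Their median log2 fold change of -2.32 went to -1.19 without the library of day 15 of lactation (fry adjusted p = 0.158) and to -0.44 with equal weight per cell in limma (adjusted p = 0.0158). S100A8 stood at 0.873 ± 0.520 CPM in gestation and 6.54 ± 1.63 CPM in lactation, and 86.9% of its reads at day 15 of lactation lay in 1 cell. No list of markers of bile duct, endothelial, stellate, macrophage, lymphocyte or red cells passed fry in any contrast, though in some of them most members moved 1 way, such as 12 of 12 stellate markers higher in gestation than in lactation (fry adjusted p = 0.245). Targets of NRF2, the transcription factor of the oxidative stress response, were lower in 17 of 22 members, but the list did not pass fry (adjusted p = 0.117). It passed the mixed form of fry (adjusted p = 0.00141). Adjusted over that list alone 10 members were lower and 1 was higher, against 1 called over all genes (HMOX1). The peroxidase PRDX1 had a log2 fold change of -1.56 (SE 0.28) and TXNRD1, thioredoxin reductase, -0.95 (SE 0.21, and -0.46 without the library of day 15 of lactation), both chosen after their values were seen.

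Camera with its preset correlation called 20 of the 42 lists between gestation and lactation, and 1 with an estimated correlation. Without the library of day 15 of lactation edgeR called 2 genes, 0 of them among the 12, while all 12 kept their direction and HMOX1 had a log2 fold change of -2.45 (SE 0.28, adjusted p = 0.0732). Without the library of day 7 it called 45 genes, 4 of them among the 12. Without any 1 of the gestation libraries before day 140 it called 1 or 2 genes, HMOX1 among them each time, and without that of days 140 to 150 it called 13. With library size as the only scaling the amino acid list had a fry adjusted p of 0.0526. The other lists that passed each lost their call in at least 1 of these fits. Periportal genes, hepatocyte markers and neutrophil markers lost it in most of the fits without 1 of the gestation libraries. Urea cycle and steroid hormone handling genes kept it in those fits.

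Over gestation 4 single genes climbed, while genes of lipid synthesis fell. PLIN2, the coat protein of lipid droplets, went from 3.77 CPM at days 40 to 50 to 103 CPM at days 140 to 150, a slope of 5.41 on the log2 scale per 100 days (SE 0.52, adjusted p = 0.0269, edgeR). SLC22A5, the carnitine transporter, went from 3.26 to 46.6 CPM (3.90, SE 0.36, adjusted p = 0.0268, edgeR). CES4A, of the carboxylesterase family, went from 0.971 to 69.7 CPM (6.05, SE 0.25, adjusted p = 0.00014, edgeR), and ABHD1, of the alpha/beta hydrolase family, from 2.37 to 60.3 CPM (4.48, SE 0.49, adjusted p = 0.0488, edgeR). ACSS2, which activates acetate for lipid synthesis, fell from 91.1 to 15.8 CPM (-2.72, SE 0.27, adjusted p = 0.0307, edgeR). The last gene called was the long noncoding RNA LOC101102683 (-4.32), chosen after its values were seen. These were all 6 genes called of 17848, 4 rising and 2 falling, with 1181 at an unadjusted p under 0.05 over the 6 stages, while with equal weight per cell in limma 5 rose and 11 fell and with DESeq2 137 and 169. Without the library of days 140 to 150 edgeR called 0 genes, and the slopes were 5.82 for CES4A and 6.42 for PLIN2 (adjusted p = 0.0639 for both), 3.24 for SLC22A5, -2.90 for ACSS2 and -4.28 for LOC101102683. That of ABHD1 went down to 2.66 (adjusted p = 0.451). Without the library of days 40 to 50, 50 to 70 or 90 to 100 edgeR called 2, 1 and 1 genes, CES4A among them each time, without that of days 100 to 120 it called 5 and without that of days 70 to 80 it called 9. The list of triglyceride storage and VLDL secretion, which holds PLIN2, did not pass fry, with a positive slope in 14 of 21 members (adjusted p = 0.141, and adjusted p = 0.427 with an estimated correlation in camera). It passed the mixed form of fry (adjusted p = 0.00132).

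Fatty acid and cholesterol synthesis fell as groups. In the fatty acid synthesis list 18 of 19 members had a negative slope (fry adjusted p = 0.0199, and adjusted p = 0.0233 with an estimated correlation in camera). Adjusted over the list alone 10 fell, against 1 over all genes. Members chosen after their values were seen were SCD, the stearoyl-CoA desaturase, with a slope of -4.48 (SE 0.53), FASN, the fatty acid synthase, with -4.35 (SE 0.58), and THRSP, a regulator of lipid synthesis, with -6.05 (SE 0.89). In the cholesterol synthesis list 20 of 21 members had a negative slope (fry adjusted p = 0.0199, and adjusted p = 0.0408 with an estimated correlation), and 17 fell adjusted over the list alone, against 0 over all genes. MSMO1, a sterol methyl oxidase, had a slope of -1.88 (SE 0.41). The squalene epoxidase SQLE had -2.88 (SE 0.37), HMGCS1, which makes HMG-CoA, -2.88 (SE 0.43), and FDPS, the farnesyl diphosphate synthase, -3.25 (SE 0.49), all chosen after their values were seen. Without the library of days 140 to 150 the fatty acid list passed fry (adjusted p = 0.0337, median slope -1.89 against -1.31 over all 6 stages) and the cholesterol list did not (adjusted p = 0.153, median slope -1.66 against -1.71). Without any 1 of the 4 libraries before day 100 the fry adjusted p of both lists lay between 0.0619 and 0.133, with median slopes of -1.29 to -1.50 and -1.69 to -1.83. Over the same stages other lists moved mostly 1 way without passing fry, with red cell markers lower in 6 of 6 members (median slope -2.70, adjusted p = 0.307), lymphocyte markers higher in 11 of 11 (0.75, adjusted p = 0.793) and immediate early and dissociation genes higher in 22 of 25 (0.72, adjusted p = 0.553).

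**Figure D2:**
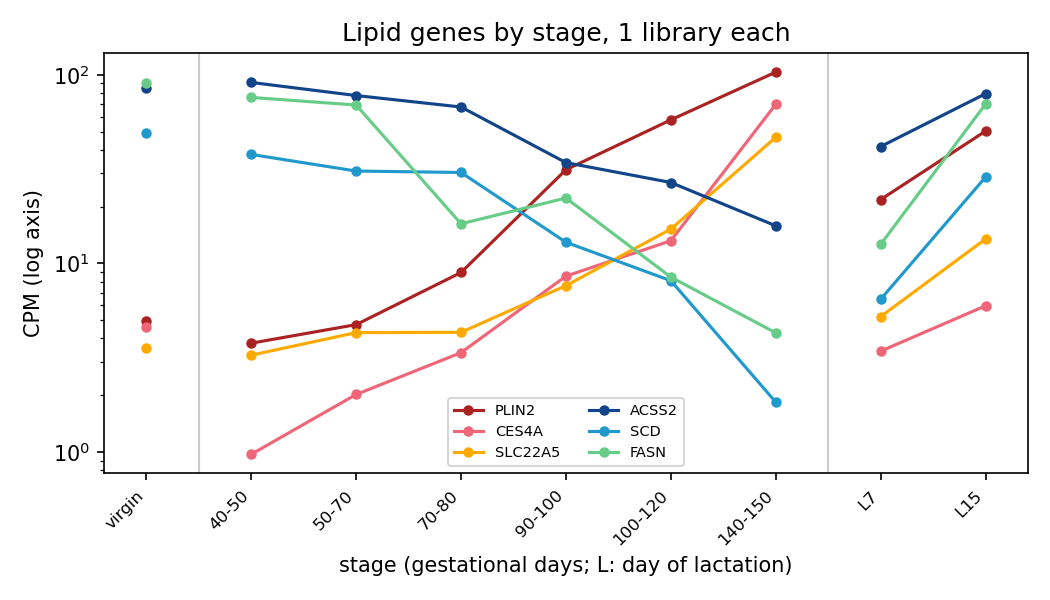
CPM on a log axis of PLIN2, CES4A, SLC22A5, ACSS2, SCD and FASN in each of the 9 stages, 1 library each, with lines joining stages of the same phase. PLIN2 climbed from 3.77 to 103 CPM over gestation while SCD went from 37.8 to 1.84 CPM, and at day 15 of lactation SCD stood at 28.7 CPM.

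**Figure D3:**
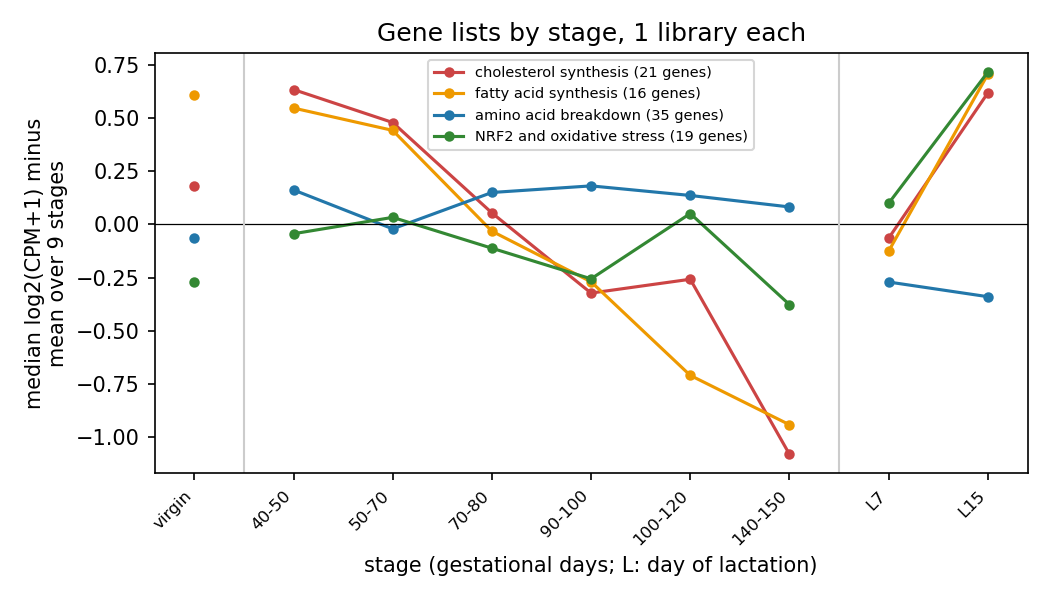
Median over the members of 4 gene lists of log2(CPM + 1) minus the gene's mean over the 9 stages, by stage, 1 library each. The cholesterol synthesis median went from 0.63 at days 40 to 50 of gestation to -1.08 at days 140 to 150 and stood at 0.62 at day 15 of lactation.

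Against the virgin sample, gestation differed in 1 of 20263 genes in edgeR, with 901 at an unadjusted p under 0.05. NNAT, an imprinted membrane protein, stood at 27.9 CPM in the virgin sample and 1.73 ± 0.515 CPM in gestation (SD, n = 6), a log2 fold change of -4.01 (SE 0.34, adjusted p = 0.00626, edgeR). Fatty acid oxidation genes were higher in gestation in 23 of 23 members (fry adjusted p = 0.0342, and adjusted p = 0.0614 with an estimated correlation in camera). Adjusted over the list alone 3 were higher, against 0 over all genes. Among them were the isomerase ECI2 (log2 fold change 0.97, SE 0.22) and the acyl-CoA dehydrogenase ACADL (0.94, SE 0.25), both chosen after their values were seen. Steroid hormone handling genes were higher in 13 of 13 members (fry adjusted p = 0.0342, and adjusted p = 0.148 with an estimated correlation), with 0 higher adjusted over the list alone and 0 over all genes. HSD17B11, a steroid dehydrogenase, had a log2 fold change of 0.66 (SE 0.30). Markers of other cells were also higher in most members, with 6 of 6 for red cells (median log2 fold change 4.01, fry adjusted p = 0.455), 10 of 11 for lymphocytes (2.56, adjusted p = 0.737) and 10 of 11 for endothelium (1.81, adjusted p = 0.324), none of which passed. The virgin phase was 1 sample and was assumed to vary like the others. In lactation, too, fatty acid oxidation genes stood above the virgin sample in 19 of 23 members (median log2 fold change 0.34). Steroid hormone handling genes did so in 10 of 13 (0.27). The virgin sample had the lowest stage median of both lists (-0.452 and -0.405, the next lowest -0.15 and -0.32). A feature of the virgin library alone was therefore not told apart from a change with gestation. Both lists lost their calls with library size as the only scaling, at a fry adjusted p of 0.23, and with several single stages left out. The median of fatty acid oxidation was 0.55, with 0.41 under library size and 0.50 to 0.58 with a stage left out, and that of steroid hormone handling 0.66, with 0.51 and 0.59 to 0.67.

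Lactation and the virgin sample differed in 0 genes in edgeR, with 1000 at an unadjusted p under 0.05, while DESeq2 called 96 and limma with equal weight per cell called 33. HMOX1 had the log2 fold change 2.92 (SE 0.42) with an adjusted p of 0.236 in edgeR over all genes and 0.000806 adjusted over the NRF2 list alone, where 3 members were higher. In the urea cycle list 7 of 10 members were lower in lactation and 4 were lower adjusted over the list alone, against 0 over all genes, but the list did not pass fry (adjusted p = 0.17). CPS1 had a log2 fold change of -1.02 (SE 0.30), and GLS2, chosen after its values were seen, -2.54 (SE 0.49). No list passed fry in this contrast, in which 6 of 6 red cell markers (adjusted p = 0.482) and 11 of 11 lymphocyte markers (adjusted p = 0.786) were higher in lactation. Also higher without passing fry were 19 of 23 fatty acid oxidation genes (adjusted p = 0.28) and 10 of 13 steroid hormone handling genes (adjusted p = 0.695). The mixed form of fry passed 6 lists, among them periportal (adjusted p = 0.00213) and urea cycle genes (adjusted p = 0.00509).

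The step across birth, from days 140 to 150 of gestation to day 7 of lactation, sets 1 library against 1 and has no replicate check, so no test was made. Sterol synthesis stood higher after birth. The median log2 difference of the cholesterol synthesis list was 1.07 (percentile 100 among 10000 random lists matched on expression), and that of fatty acid synthesis was 0.80 (percentile 100). NRF2 targets (0.58, percentile 100), the acute phase response (0.33, percentile 99.8) and interferon response genes (0.21, percentile 98.7) also stood higher. Periportal genes (-0.73, percentile 0), amino acid breakdown (-0.56, percentile 0) and apolipoproteins (-0.88, percentile 0.01) stood lower. In all, 15 of 35 lists lay outside the central 95% of the random lists. The random lists were drawn gene by gene, so they do not carry the correlation between members of a real list. Their range is thus likely too narrow, and no other pair of stages was compared in this way. Among single genes THRSP stood at 5.37 CPM before birth (95% exact Poisson interval 5.06 to 5.71) and 75.4 CPM after it (73.8 to 76.9). KRT79, a keratin, went from 8.72 to 124 CPM and CSAD, of taurine synthesis, from 29.8 to 156 CPM. FDPS, the drug-conjugating enzyme UGT2B7 and the transcription factor ATF5 were also among the 8 with the largest fold toward day 7. HBB, a haemoglobin chain, stood at 0.642 and 222 CPM, with 97.7% of the later reads in 1 cell, and JCHAIN, of antibodies, at 19.1 and 94.9 CPM, with 91.4% in 1 cell. In the other direction PDK4, which holds back pyruvate oxidation, stood at 444 CPM before birth (441 to 447) and 29.1 CPM after it (28.2 to 30.1). The immune adhesion molecule JAML stood at 138 and 1.86 CPM, the glutamate transporter SLC1A2 at 62.7 and 0.353 CPM, and APOA4, a lipid-carrying apolipoprotein, at 86.1 and 5.66 CPM. CES4A and ABHD1 stood lower too, at 3.42 and 3.79 CPM after birth, as did C1H3orf85 (97.8 and 11.9 CPM) and GOT1, an aspartate aminotransferase (257 and 35.8 CPM).

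Measures over cells were compared between gestation and lactation with two-sided exact permutation tests over the stages, where 6 against 2 stages allow a smallest p of 0.0714. The Spearman correlation across cells between pericentral and periportal scores, a measure of lobular zonation, was -0.518 ± 0.102 in gestation and -0.370 ± 0.197 in lactation (difference -0.148, exact p = 0.214, with -0.00877 without day 15 of lactation and -0.287 without day 7). The median number of genes detected per cell, at 155164 reads per cell, was 5496 ± 595 in gestation and 5862 ± 146 in lactation (difference -366, exact p = 0.5, with -189 without days 100 to 120 of gestation). Cells with reads for at least 3 of 10 cell cycle genes made up 6.60 ± 8.33% in gestation and 4.55 ± 3.00% in lactation (difference 2.05 percentage points, exact p = 0.857). Their share was 23.5% at days 70 to 80 of gestation (95% exact binomial interval 17.9 to 29.8%) and 13.3% in the virgin sample (10.4 to 16.7%), and between 1.69% and 6.67% in the other 7 stages. Without the stage of days 70 to 80 the difference turned to -1.32 percentage points, and without day 15 of lactation to -0.0683. With reads for at least 2 of the genes required, it was 0.336 percentage points (exact p = 0.786). The share was then 61.0% at days 70 to 80. The virgin sample (39.9%) no longer stood apart from days 50 to 70 (39.7%) or day 7 of lactation (40.9%).

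**Figure D4:**
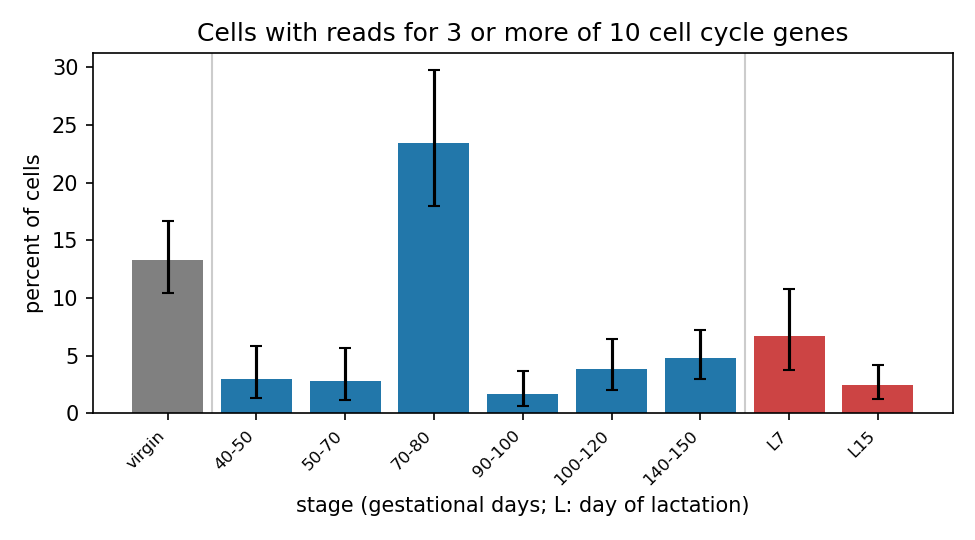
Percent of cells with reads for at least 3 of 10 cell cycle genes at 155164 reads per cell, by stage, with exact 95% binomial intervals that cover counting error only. The share was 23.5% at days 70 to 80 of gestation and 13.3% in the virgin sample.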

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

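The tests of explanations below, other splits of the samples included, were all chosen or worded after the results they bear on were seen, except for the rule for samples far from the others, which was fixed beforehand, and the test of HMOX1 by dissociation score, which was written before its values were seen. Of 69 sets of 6 gestation values, 13 had a highest or lowest stage whose gap to its neighbour was large for the range of the set (above Dixon's 95% critical value, 0.625), and chance alone gives that in about 1 in 20 sets without a trend. The library of days 140 to 150 had such a gap for ABHD1 (60.3 CPM), APOA4 (86.1 CPM), CES4A (69.7 CPM), GK (232 CPM) and SLC22A5 (46.6 CPM), each the highest of the 6. A steep rise leaves such a gap by itself, and without that library the slope on the log2 scale per 100 days was 5.82 for CES4A (6.05 with it), 3.24 for SLC22A5 (3.90) and 1.86 for GK (2.43). For ABHD1 it went from 4.48 to 2.66 and for APOA4 from 7.53 to 3.16, so for these 2 the library stood apart from the rise over the other stages. The library of days 140 to 150 also had such a gap for DBT (51.9 CPM). That of days 70 to 80 stood apart for AASS (58.5 CPM), SRD5A2 (33.6 CPM) and the share of cells with cell cycle transcripts (23.5%). That of days 50 to 70 stood apart for ASL (139 CPM) and SLC7A2 (61.6 CPM), that of days 90 to 100 for C1H21orf62 (4.08 CPM), and that of days 100 to 120 for the median of the immediate early and dissociation list (1.25). Reads on rows that name no gene, which no comparison uses, reached 0.799% at days 70 to 80 against 0.472% in the virgin sample, and 4 stages lay above the virgin share.

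Genes of fatty acid and cholesterol synthesis fell together over gestation, and a shift in the lobular position of the picked cells is argued against, since within each of 3 groups of 620 or 621 cells, ordered by the zonal score, at least 94.8% of the slope over all cells was kept, and so are a few deeply sequenced cells, since with equal weight per cell the higher fry adjusted p of both lists was 0.0272. Of 100 orders of the gestational days 1, the real one, gave as many of the 42 lists passing fry (2, the highest other 1), so chance order is argued against, though in 3 of them, the real one included, the lowest p of any list was as low. The library of days 140 to 150 as the sole reason is argued against, since without it the median over members of log2(CPM + 1) had a slope per 100 days of -1.572 (SE 0.20, 95% interval -2.22 to -0.93) for fatty acid synthesis and -1.516 (SE 0.28, -2.39 to -0.64) for cholesterol synthesis, against -1.36 (SE 0.14) and -1.71 (SE 0.17) over all 6 stages. The call of the cholesterol list ended without that library (fry adjusted p 0.153), while the fatty acid list passed (0.0337). Why the call ended was not tested. What stays open is anything particular to 1 animal or 1 day of collection, which the labels do not name, and a change of lipid synthesis with gestational day may be the reason, as a hypothesis.

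HMOX1 was higher in lactation than in gestation. Macrophages or red cells among the picked cells are argued against, since among cells with no read for their markers HMOX1 was detected in at least 79.4% of lactation cells (day 15, 95% interval 72.7 to 85.2%) and at most 34.5% of gestation cells (days 70 to 80, 17.9 to 54.3%). Most cells of every stage had a marker read. Those without one were 29 of 213 at days 70 to 80, 59 of 225 at day 7 of lactation and 175 of 495 at day 15. Stress from taking the cells apart is argued against as the sole reason, since within each of 3 groups of cells by immediate early and dissociation score HMOX1 was detected in at least 73.81% of lactation cells and at most 56.1% of gestation cells, with 95% intervals apart within each group over stages with at least 20 cells (of the 2 with fewer, 1 stood at 64.7% of 17 cells). Of 28 splits of the 8 stages 1, the real one, called as many genes as the 12 (the highest other called 4), so chance is argued against for the set. The biological difference between the phases may account for it, but an unnamed batch shared by both lactation libraries was not tested.

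Cells with cell cycle transcripts made up 23.5% at days 70 to 80 of gestation. Immune cells as most of these cells are argued against, since 14% of them (7 of 50, 95% interval 5.82 to 26.7%) had a read for PTPRC. Of the other cells of that stage 6.13% had one, so some immune cells among them are not excluded. The mean log2(CPM + 1) of ALB, TTR and FGB was 14.59 in these cells and 14.79 in the others. Other cell types without PTPRC were not tested. A difference in reads per cell is argued against, since the share of 23.47% was taken at 1 depth and its lower limit of 17.9% lay above the upper limits of the other 5 gestation stages. At that depth the cells of this stage had the most genes detected (median 6391, the other gestation stages 4611 to 5820), and among cells with 5738 to 6956 genes the share was 24.3% (16.5 to 33.5%), above the upper limits of 4 of the other gestation stages (10.1% at most), while days 100 to 120, with 16 such cells, had an upper limit of 38.35% and stay open. The virgin sample, with 255 such cells, stood at 12.55% (8.74 to 17.25%), and its interval overlapped that of days 70 to 80. TPX2 and BIRC5, which count among the 10 genes, were detected in many cells of every stage, so the share may include cells that were not dividing, and with 1 library at this stage, no biological explanation was tested.

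For the trend in single genes, 1 of 100 orders of the days, the real one, gave as many as the 6 genes called (the highest other gave 5), so chance order is argued against. For gestation against virgin, 3 of the 7 ways to set 1 of the 7 stages apart gave at least the 1 gene called (the highest other gave 6), and 7 ways are too few for a share under 0.05.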

How the results depend on the processing

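In all 4 contrasts the count of called genes changed most with the DESeq2 Wald test, while equal weight per cell, run in limma, changes the weights and the test together. Between gestation and lactation edgeR called 12 genes, with library size as the only scaling 22 (11 of them among the 12, 6 higher and 16 lower), without a filter 21 (all 12, 13 higher and 8 lower), with the DESeq2 Wald test 523 (all 12, 355 higher and 168 lower) and with equal weight per cell in limma 6 (3 of the 12, 0 higher and 6 lower). Between gestation and virgin the count of 1 became 5 without a filter (all lower), 117 with DESeq2 (88 higher, 29 lower), 57 with equal weight per cell (2 and 55) and 3 at 1 depth (all lower). Between lactation and virgin the count of 0 became 96 with DESeq2 (42 higher, 54 lower) and 33 with equal weight per cell (1 and 32). The trend count of 6 became 17 without a filter (9 rising, 8 falling), 306 with DESeq2 (137 and 169), 16 with equal weight per cell (5 and 11), 9 at 1 depth (4 and 5), 2 with stage order in place of days (2 and 0), 2 with the virgin sample at day 0 (0 and 2), and 8 with the filter added after the data were seen. Leaving out 1 stage gave 1 to 45 genes between gestation and lactation, 1 to 2 between gestation and virgin, 0 to 1 between lactation and virgin, and 0 to 9 for the trend. With an estimated correlation camera called 1, 0, 0 and 2 lists in the 4 contrasts, against 20, 16, 16 and 14 with the preset one. Library size alone shifted the median of all genes by -0.19 on the log2 scale between gestation and lactation and by -0.14 between gestation and virgin, and equal weight per cell by -0.16 in both. The list calls that ended with them are given here as fry adjusted p. With library size alone these were 0.134 for periportal, 0.134 for urea cycle, 0.0526 for amino acid breakdown, 0.268 for steroid hormone handling and 0.057 for hepatocyte markers between gestation and lactation, and 0.23 for both fatty acid oxidation and steroid hormone handling against virgin. With equal weight per cell they were 0.0611 for periportal, 0.0612 for urea cycle, 0.229 for steroid hormone handling and 0.0609 for hepatocyte markers, and 0.225 for both lists against virgin. Neutrophil markers had 0.0812 at 1 depth, and cholesterol synthesis 0.179 with the virgin sample at day 0. No such median turned, though that of steroid hormone handling between gestation and lactation went from 0.24 to 0.05 with library size alone and to 0.02 with equal weight per cell, amino acid breakdown from 0.44 to 0.25 and 0.27, periportal from 0.51 to 0.33 and 0.34, and hepatocyte markers from 0.56 to 0.36 and 0.29. Neutrophil markers went from -2.32 to -0.44 with equal weight. Without day 15 of lactation steroid hormone handling stood at 0.54, neutrophil markers at -1.19 and hepatocyte markers at 0.34, and cholesterol synthesis went from -1.71 to -1.08 with the virgin sample at day 0. Leaving out 1 stage gave ranges of 0.0197 to 0.183 for periportal, 0.0119 to 0.0969 for urea cycle, 0.000553 to 0.0469 for amino acid breakdown, 0.0203 to 0.0954 for steroid hormone handling, 0.0156 to 0.158 for neutrophil markers and 0.0349 to 0.183 for hepatocyte markers between gestation and lactation. They were 0.0145 to 0.0744 for fatty acid oxidation and 0.0315 to 0.0744 for steroid hormone handling against virgin, and 0.0309 to 0.103 for fatty acid synthesis and 0.0309 to 0.153 for cholesterol synthesis over gestation. With 1 stage left out the difference in cells with cell cycle transcripts ran from -1.32 to 4.17 percentage points and turned without days 70 to 80 (-1.32) and without day 15 of lactation (-0.0683), that in zonation from -0.287 to -0.00877, and that in genes detected from -545 to -189. With cells thinned to the 25th percentile of reads per cell, the difference in genes detected was -588. The cause of these changes was not tested. Of the values of single named genes under alternatives, 713 kept their side of the threshold or, across birth, their range, 53 passed the threshold, 124 no longer passed it, 28 moved and none turned. The 713 include genes called neither in the main fit nor under the alternative, so they do not measure how stable the calls were. Only the 12, 1 and 6 genes called in the main fits could lose a call, and all 124 losses are theirs. The 28 that moved all belong to the step across birth. There, most folds with library size alone or equal weight per cell left the range set by the Poisson intervals. The authors' normalized table held 0 values, so that alternative was not run. The filter on genes detected and mitochondrial reads per cell removed 0 cells, and with 0 sheep named no fit by animal was made, so neither says anything of stability.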

Other observations

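The test of HMOX1 against other NRF2 targets and that of acute phase RNA were written before their results were seen, and the spread used to judge both was added afterwards. Stages differed in gene groups that no comparison covers, given here as the median of log2(CPM + 1) minus the mean over the 9 stages. Day 7 of lactation stood highest for the acute phase list (0.55, against -0.62 at day 15), with ORM1, an acute phase glycoprotein, at 9781 CPM against 115 CPM at day 15 and LBP, which binds bacterial lipopolysaccharide, at 498 against 140 CPM. It also stood highest for interferon response genes (0.67), followed by the virgin sample (0.37), where ISG15 stood at 205 CPM. Day 15 of lactation stood highest for NRF2 targets (0.72), with SRXN1, which repairs peroxiredoxins, at 73.7 CPM against 22.7 CPM at day 7. Fatty acid synthesis stood at 0.71 at day 15 and -0.13 at day 7, with FASN at 69.9 and 12.6 CPM. All genes in these sentences were chosen after their values were seen, and with 1 library per stage none of these differences has a test.

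Days 100 to 120 of gestation stood highest for immediate early and dissociation genes (1.25, the next stage at 0.24), with JUN at 26.0 CPM, and also for ribosomal proteins (0.40) and clock genes (0.40). The cell cycle list stood highest at days 70 to 80 (0.94) and in the virgin sample (0.71), with TOP2A, the topoisomerase of dividing cells, at 27.8 and 20.7 CPM against 6.37 CPM or less in the other stages, both genes chosen after their values were seen.

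If HMOX1 in lactation marked cells with an oxidative stress response, cells with more HMOX1 RNA could be predicted to hold more RNA of other NRF2 targets. Of the 22 list members, HMOX1 included, 18 others had enough reads per cell on average to be used. The Spearman correlation across cells was 0.122 at day 7 (225 cells, 95% interval -0.007 to 0.26) and 0.088 at day 15 (495 cells, 0.002 to 0.175). They lay at percentiles 72.7 and 82.7 of 1000 random lists matched on expression, whose upper limit was 0.2 at day 7 and 0.128 at day 15. The rule set beforehand asked for correlations above these limits on both days, and by it the prediction was not met. Each interval reaches the limit of its own day, so by the spread added afterwards the test leaves the idea open.

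Cells carrying immune or blood RNA might have set the acute phase level at day 7 of lactation. Over cells with no read for lymphocyte, macrophage, neutrophil or erythroid markers the difference from days 140 to 150 of gestation was 109.6% of that over all cells (95% interval 61.7 to 159.2% over resampled cells), which argues against this. It rests on 30 and 87 such cells.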
